A study of Rattus norvegicus with 10 samples.

How the data were processed

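Liver RNA of 10 Wistar Han rats was measured on Affymetrix rat expression arrays, 1 array per animal. The labels put 5 rats in a vehicle group (deionized water) and 5 in a group given RG3487 at 180 mg/kg by gavage, in a volume of 5 ml/kg. The rats were 6 to 8 weeks old, and a piece of the left lateral lobe was kept in a stabilising solution before RNA extraction. Labelling started from 1 ug of RNA. The sample titles and source names place the livers at 24 h after the dose, whereas the series design text names 2 h. The time is given here as the 24 h of the samples. Sex, scan date and array batch are not given in the sources used here. Rats were housed in groups of 5, so housing group and treatment may coincide and cannot be told apart. The titles number the rats within each group and the source names give 10 different animals, so the numbers were not used to pair them.

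The deposited table holds an Affymetrix signal intensity per probe set on a linear scale, in whole numbers, made with MAS5 per the labels. The MAS5 version and scaling target are not given in the sources used here. The array means lay between 330 and 332, so the deposited intensities had been scaled to a common mean. Detection calls were not used here. For arrays there is no read depth, and the number of arrays per group limits the precision.

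The table lists 15899 probe sets, of which 40 are controls. Of the other 15859, 12562 carried 1 gene in the platform annotation, 332 carried several and 2965 carried none. Symbols were looked up through the Entrez identifier or a sequence accession and otherwise kept as annotated, and 1 symbol changed. Genome coordinates were not used here.

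Signals were analysed as log2 of signal plus 16. This pseudocount makes the fold of a dim gene smaller than the ratio of its mean signals, and every fold below is on that scale. Control probe sets and the 25% of probe sets with the lowest mean log2 signal over all 10 arrays were left out, which left 11894. The groups were compared with limma (lmFit, then eBayes with a mean-variance trend), and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05. These p-values are two-sided. A gene was represented by its retained probe set with the highest mean among those with 1 symbol, which gave 7727 genes. Values per array and control probe sets were compared with an exact two-sided permutation test over all 252 regroupings of the 10 animals, whose smallest possible p is 0.00794.

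The design, the 39 gene lists, the rule for naming genes and all alternatives except spike-in scaling were fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and p was adjusted over the 32 lists tested. Beside it stand camera with an estimated correlation, fry, which tests whether the members of a list move one way on balance, and an exact permutation test of each animal's mean over the list. Within each list, p was also adjusted over the list alone. Genes named are the 12 largest increases and 12 largest decreases among genes past the threshold, up to 4 members with the smallest p in each tested list (2 where none passed), and a set of genes chosen for the compound or for liver toxicology. Other genes named were chosen after their values were seen, and the text says so. A further 26 lists were written after the first results. Of these, 5 were corrected after their counts had been seen, because their name patterns had taken in genes outside the family, and both forms are given.

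The alternatives were pseudocounts of 1 and 64, quantile normalization, centring of each array on its median, no filter or a filter on the dimmest 50%, eBayes without trend or with robust estimation, and array weights. Further alternatives were the replicate number as a block, a fold threshold of 1.5, an adjusted p under 0.1, an exact rank-sum test, other choices of probe set, and each array left out in turn. Scaling by the hybridization controls, bacterial and phage transcripts added to each sample, was added after seeing the data. It assumes that equal amounts were added to all samples, which the sources used here do not show. The same counts were made for 100 of the 126 splits of the 10 animals into groups of 5. Each group of 5 values was checked for a single far value with Dixon's ratio, with a critical value of 0.710.

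The code was tested on simulated data for the comparison of RG3487 with vehicle. With 200 of 11894 probe sets changed in each of 20 data sets, limma found 28.4% of those changed 1.25-fold, 77.3% at 1.5-fold and 96.2% at 2-fold, and 4.11% of its calls were false. The exact rank-sum test made 0 calls there, since its smallest p cannot pass adjustment when few probe sets change. Among 7727 genes, a list shifted by 0.25 on the log2 scale was found in 20 of 20 data sets by camera with either correlation and in 0 by the exact test over animals. The simulated genes varied independently, whereas the estimated correlation here was 0.526 among ribosomal protein genes and 0.204 among PPAR-alpha targets. These rates therefore do not carry over to lists of correlated genes. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.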

Results

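Gene expression was measured on 10 arrays of rat liver, 5 from rats given deionized water and 5 from rats given RG3487 at 180 mg/kg by mouth. RG3487 is known to bind the nicotinic receptor encoded by Chrna7 and the serotonin receptor encoded by Htr3a. Neither gene was represented by a probe set of its own, so neither was analysed here. The samples are labelled 24 h after dosing, while the series text states 2 h. The mean signal of the arrays lay between 330 and 332, and the number of arrays limits the precision. The median signal was 88.6 ± 2.6 (SD, n = 5) in the vehicle group and 94.4 ± 1.5 (n = 5) with RG3487 (exact permutation p = 0.00794, adjusted p = 0.019 over 12 array measures), and the maximum was 10784 ± 399 and 9771 ± 433. Correlations of log2 signal were 0.977 to 0.986 between arrays of the same group and 0.960 to 0.976 between groups, and the first principal component, with 40.6% of the variance, separated the groups.

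The comparison asked which liver transcripts differed between rats given RG3487 and rats given vehicle. Cyp1a1, a monooxygenase gene induced through the aryl hydrocarbon receptor, showed the largest increase with a pseudocount of 16, from a signal of 14.6 ± 9.6 to 258 ± 82 (SD, n = 5 per group; log2 change 3.17 ± 0.23 SE, 9.02-fold, adjusted p = 1.13e-05). Inmt, which encodes a methyltransferase, showed the largest decrease, from 1183 ± 459 to 169 ± 53 (log2 change -2.64 ± 0.31, 6.25-fold lower, adjusted p = 0.000207). Of NRF2 targets 14 of 20 rose, and of p53 targets 9 of 15 rose and 2 fell. Of PPAR-alpha targets 16 of 30 fell, as did 14 of 20 genes of gluconeogenesis and fasting and 19 of 31 complement and coagulation factors. These 5 lists passed with a preset correlation between genes. With an estimated correlation the fasting list and the complement and coagulation list passed (adjusted p = 0.0439 each), while the NRF2 (0.223), p53 (0.223) and PPAR-alpha (0.0528) lists did not.

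The other large increases were those of Vxn (log2 change 2.98 ± 0.40), Mybl1 (2.74 ± 0.30), the clock output gene Dbp (2.47 ± 0.38), the cytochrome P450 gene Cyp2c12 (2.27 ± 0.24), the glutathione transferase genes Gstm3 (2.16 ± 0.23) and Gsta3 (1.68 ± 0.25), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.14 ± 0.45). Phlda3, a p53 target, rose by 2.06 ± 0.17, the aldo-keto reductase gene Akr7a3 by 1.90 ± 0.37, Cryl1 by 1.61 ± 0.19, and Nfe2l2, which encodes the transcription factor NRF2, by 1.60 ± 0.09 (662.8 to 2033, adjusted p = 2.5e-06). Large decreases were those of Insig1, a regulator of sterol synthesis (-2.24 ± 0.32), Igfbp1 (-2.10 ± 0.53), Ehhadh, a peroxisomal enzyme of fatty acid oxidation (-2.03 ± 0.23, 4.08-fold lower), Mfsd2a (-1.80 ± 0.32), Nupr1 (-1.78 ± 0.16) and Cyp17a1, a steroid hydroxylase (-1.75 ± 0.22). Rab30 changed by -1.74 ± 0.21, Pdk4, which restrains glucose oxidation, by -1.64 ± 0.31, the lipase inhibitor Angptl4 by -1.62 ± 0.19, Nim1k by -1.51 ± 0.14 and Stac3 by -1.48 ± 0.35. In 22 of these 24 genes the groups did not overlap. The exceptions were Cyp7a1 and Igfbp1, which did not pass the exact rank-sum test (adjusted p = 0.0647, range 0.000868 to 0.0647 over the alternatives, and 0.1, range 0.0051 to 0.1). A probe set without a gene name, the third in size of decrease, had a log2 change of -2.16 ± 0.47. Folds of dim genes moved with the pseudocount: that of Cyp1a1 was 19.3 with a pseudocount of 1 and 4.03 with 64, and those of Vxn were 13.5 and 4.03. With 64, that of Cyp2c12 (4.08) lay above both. Those of Mybl1, Dbp, Gstm3, Cyp7a1, Phlda3, Nim1k and Stac3 also moved by more than 1.5 times.

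**Figure D1:**
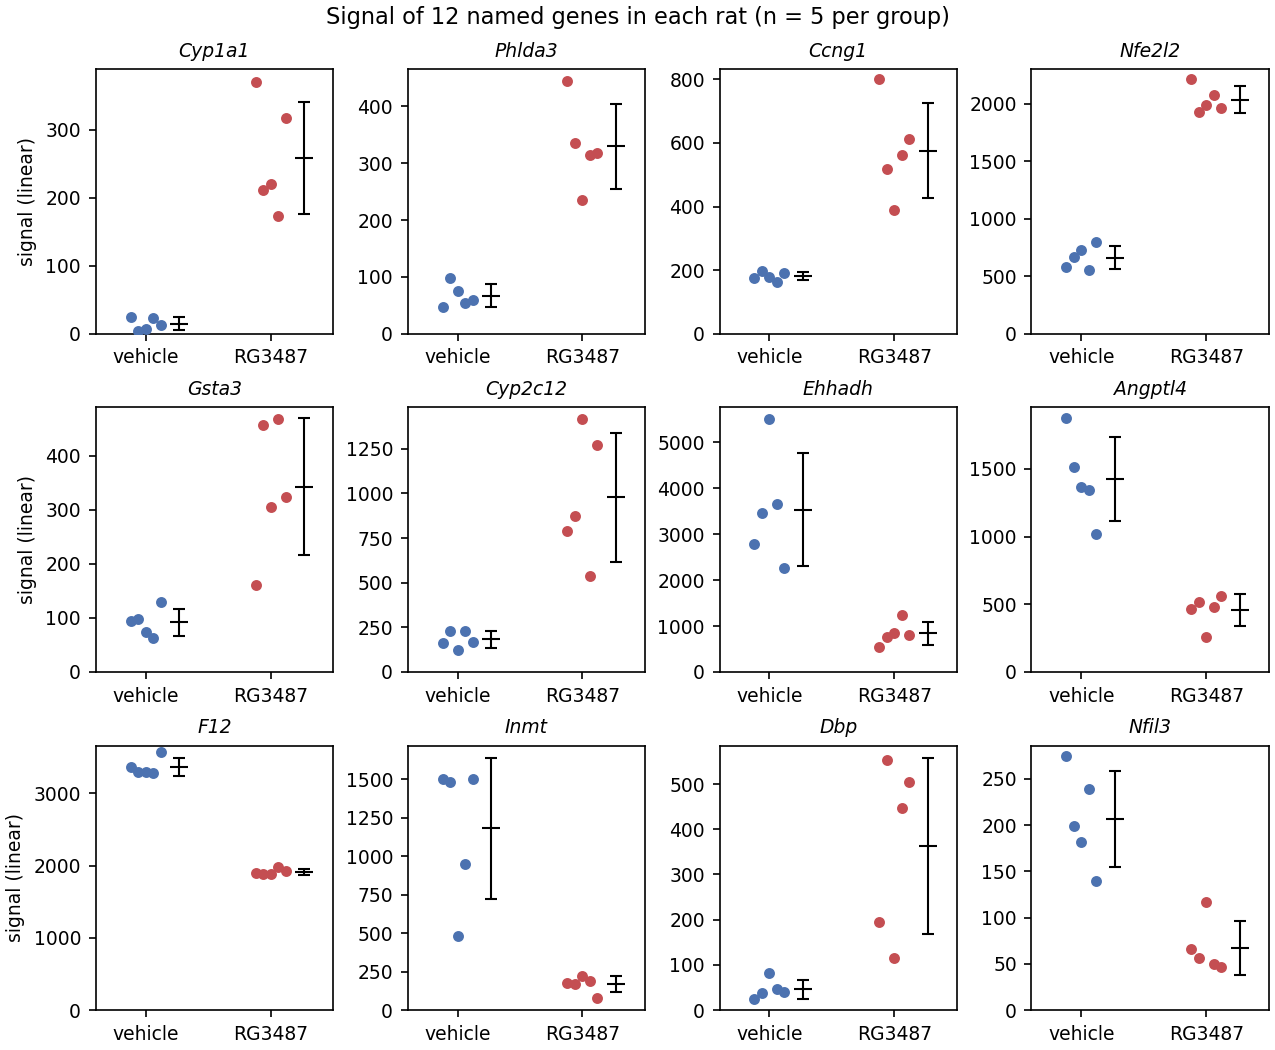
Signal on a linear scale of 12 named genes in each rat, with 5 vehicle rats in blue and 5 RG3487 rats in red, and the mean with its SD beside the points. Cyp1a1 rose from a mean of 14.6 to 258, Inmt fell from 1183 to 169, and the groups did not overlap in either gene.

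Of 11894 probe sets tested, 3295 passed limma's test (2443 higher and 852 lower), and 462 of them changed at least 1.5-fold (249 higher and 213 lower). Among 7727 genes, 2296 passed (1724 higher and 572 lower). The groups did not overlap in 2187 probe sets, 18.4% of those tested, where chance gives 0.794%. The balance of higher and lower depended on the scaling of the arrays: 74.1% of calls were higher as deposited, 54.4% with quantile normalization (1423 higher and 1193 lower), 45.1% with arrays centred on their median (1194 and 1454) and 95% with spike-in scaling (6683 and 354). The hybridization controls are bacterial and phage transcripts added to each sample, and several of their 18 probe sets read the same transcript. They averaged 9.90 on the log2 scale in the vehicle group and 9.71 with RG3487 and were lower in 18 of 18 probe sets. Scaling to them assumes that equal amounts were added to all samples, which the sources used here do not show. The 95% needs at least that assumption. Labelling started from 1 ug of RNA in each sample, so even then the 95% does not measure amounts of RNA in the liver. Spike-in scaling moved the median change of all genes from 0.0944 to 0.29. List medians in this part are therefore given relative to the median of all genes unless called unadjusted. Genes were higher more often than lower except among the 773 brightest, where 178 were higher and 209 lower. The fixed lists were not compared with random lists matched on signal.

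**Figure D2:**
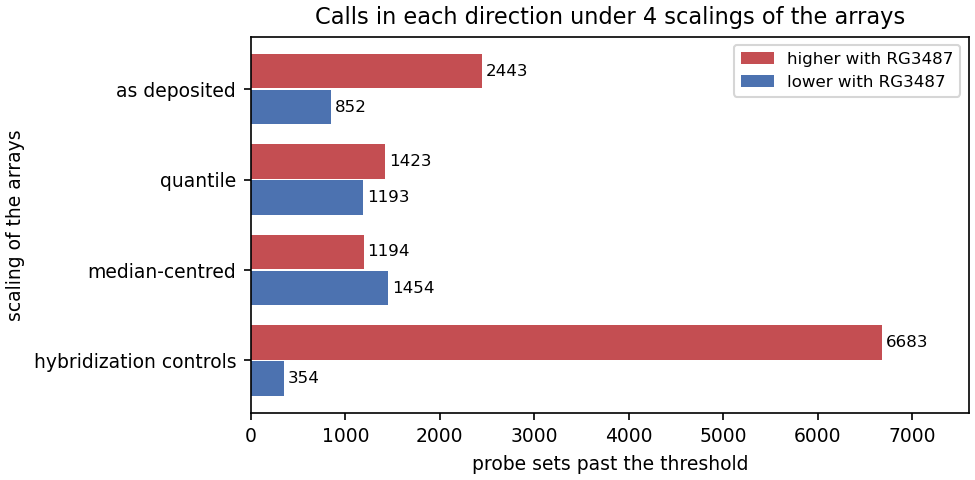
Number of probe sets past the threshold (horizontal axis) that were higher or lower with RG3487, under 4 scalings of the arrays. Lower calls outnumbered higher ones when arrays were centred on their median (1454 against 1194), and higher ones outnumbered lower ones under the other 3 scalings.

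**Figure D3:**
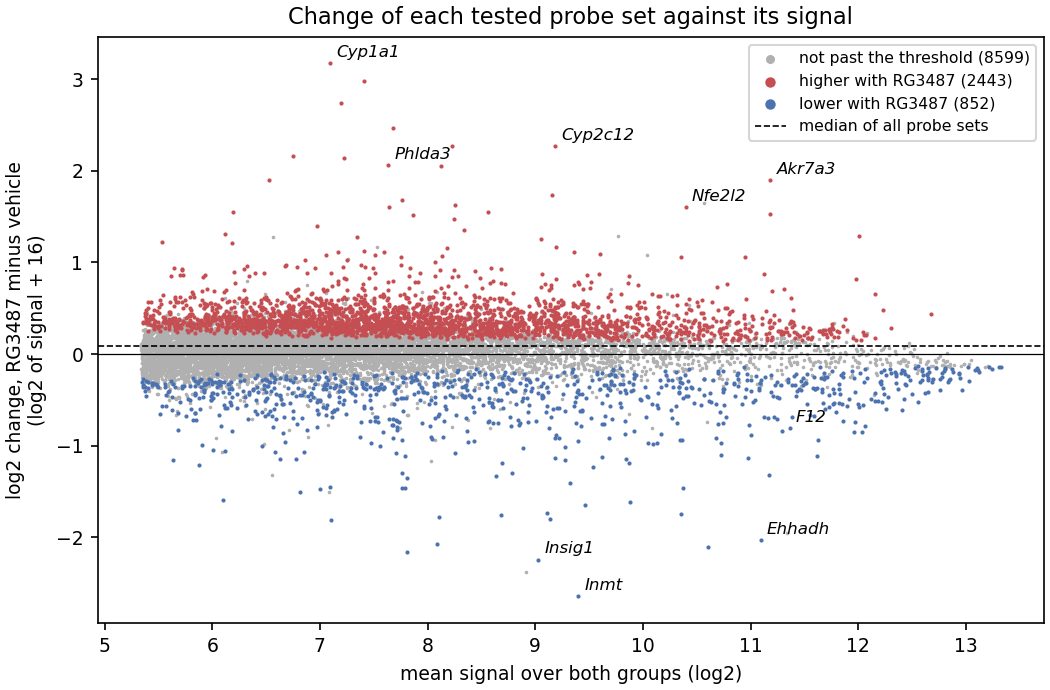
Log2 change (RG3487 minus vehicle, as deposited) of each of 11894 probe sets against its mean signal on a log2 axis, with those past the threshold in red (2443 higher) and blue (852 lower) and a dashed line at the median of all probe sets, 0.0826. Named genes are marked, with Cyp1a1 the largest increase and Inmt the largest decrease at the pseudocount of 16 used here.

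NRF2 targets, genes of the antioxidant response, rose: 14 of 20 measured were higher and 0 lower, also when adjusted over the list alone, with Ephx1 at 1.29 ± 0.17 (2424 to 5801), Gsta3, Tkt at 0.61 ± 0.10 and Gstm1 at 0.44 ± 0.05. Their median lay 0.361 above that of all genes (adjusted p = 0.000142, and adjusted p = 0.223 with an estimated correlation). Of p53 targets, 9 of 15 rose and 2 fell, or 10 and 2 adjusted over the list alone. Besides Phlda3, Ccng1 rose by 1.55 ± 0.15, Aen by 1.08 ± 0.13 and Mdm2, a negative regulator of p53, by 0.97 ± 0.11. The 2 that fell, named after their values were seen, were Gadd45a (-0.51 ± 0.12) and Sesn2 (-0.59 ± 0.18). With spike-in scaling, in contrast, 11 targets were higher and 0 lower. The p53 list passed (0.590 above all genes, adjusted p = 0.00331), but not with an estimated correlation (adjusted p = 0.223) or spike-in scaling (adjusted p = 0.0677; range over alternatives 0.000145 to 0.223). Cdkn1a, a p53 target that halts the cell cycle, changed by 0.50 ± 0.24 and did not pass (adjusted p = 0.138), but did with spike-in scaling (0.69, adjusted p = 0.0217) and with the replicate number as a block (adjusted p = 0.0305; range 0.0217 to 0.286), and its value was 0.29 without RG3487 animal 1.

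Of 30 PPAR-alpha targets, genes of fatty acid oxidation, 16 fell and 0 rose (19 and 0 adjusted over the list alone). Their relative median was -0.47 (adjusted p = 7.7e-16, and adjusted p = 0.0528 with an estimated correlation). Beside Ehhadh and Angptl4, Pex11a changed by -1.33 ± 0.17, Cyp4a1 by -0.85 ± 0.12 and Decr1 by -0.55 ± 0.06. Genes of gluconeogenesis and fasting fell in 14 of 20 and rose in 0 (15 and 0 adjusted over the list alone; relative median -0.80, adjusted p = 7.62e-11). These included Gpt, an aminotransferase (-0.94 ± 0.19), and Lpin1 (-0.93 ± 0.15). Pck1, the gluconeogenic enzyme gene, fell by 0.20 as deposited, but did not pass with quantile normalization (adjusted p = 0.675) or spike-in scaling (0.945; range 0.00336 to 0.945). With spike-in scaling, 1 member of each of these lists was higher, against 13 lower PPAR-alpha targets and 10 lower fasting genes.

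Complement and coagulation factors fell in 19 of 31 and rose in 0 (22 and 0 adjusted over the list alone; relative median -0.36, adjusted p = 1.49e-16), although 6 were higher and 12 lower with spike-in scaling. F12 fell from 3360 to 1912 (-0.81 ± 0.04, adjusted p = 2.03e-06), Cfi changed by -0.61 ± 0.06, Proc by -0.55 ± 0.04 and F9 by -0.49 ± 0.05. Acute phase genes fell in 12 of 26 and rose in 1, Stat3, named after its value was seen (18 and 1 adjusted over the list alone; relative median -0.29, adjusted p = 3.07e-11, and adjusted p = 0.0558 with an estimated correlation), although with spike-in scaling 4 were higher and 5 lower. Cp changed by -0.50 ± 0.05 and Itih4 by -0.42 ± 0.05, while C3 (-0.29 ± 0.04) and Itih3 (-0.31 ± 0.04) did not pass with spike-in scaling (adjusted p = 0.0945, range 0.000546 to 0.0945, and 0.0561, range 0.000344 to 0.0561).

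Glucocorticoid-responsive genes fell in 7 of 18 and rose in 0 (8 and 1 adjusted over the list alone; relative median -0.38, adjusted p = 3.09e-05), with 3 higher and 6 lower under spike-in scaling. Serpina6, which encodes the glucocorticoid carrier of plasma, changed by -1.13 ± 0.15 and Hsd11b1 by -0.56 ± 0.12. This list, the complement and coagulation list and the fasting list were the 3 that also passed with an estimated correlation (adjusted p = 0.0439 each). In bile acid synthesis and transport, 3 of 17 rose and 7 fell (4 and 9 adjusted over the list alone), a balance that turned to 6 higher and 4 lower with spike-in scaling. Abcc2, an export pump, rose by 0.88 ± 0.10, whereas Nr0b2, a repressor of Cyp7a1, changed by -1.35 ± 0.23 and Cyp27a1 by -0.76 ± 0.09. The bile acid list passed (relative median -0.30, adjusted p = 0.00231), but not with an estimated correlation (adjusted p = 0.0605) or with quantile normalization (adjusted p = 0.155; range 0.000346 to 0.221).

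Urea cycle and amino acid genes fell in 13 of 27 and rose in 3 (15 and 3 adjusted over the list alone; relative median -0.34, adjusted p = 7.81e-06, and adjusted p = 0.314 with an estimated correlation; range 1.3e-09 to 0.314), with 8 higher and 6 lower under spike-in scaling, and did not pass under fry or the exact permutation either. Otc changed by -0.68 ± 0.11, Mat1a by -0.43 ± 0.07 and Nags by 0.65 ± 0.10. Among growth hormone and sex-dependent genes only Cyp2c12 rose and 8 of 22 fell, the same counts as adjusted over the list alone, among them Serpina3m (-0.70 ± 0.07) and Ghr (-0.41 ± 0.06). Its relative median was -0.25 (adjusted p = 2.46e-05, and adjusted p = 0.153 with an estimated correlation), and the counts were 4 higher and 4 lower with spike-in scaling. The list did not pass with quantile normalization (adjusted p = 0.361; range 6.6e-06 to 0.361). In the endoplasmic reticulum stress list 7 of 22 fell and 0 rose (9 and 0 adjusted over the list alone; relative median -0.26, adjusted p = 1.8e-06, and adjusted p = 0.223 with an estimated correlation), and its unadjusted median turned positive with spike-in scaling (0.03). Sdf2l1 changed by -0.58 ± 0.10, the chaperone gene Pdia6 by -0.44 ± 0.07 and Ddit3 by -0.40 ± 0.08. Immediate early genes fell in 2 of 14, Btg1 (-0.58 ± 0.09) and Ier2 (-0.56 ± 0.17), and rose in 0, also when adjusted over the list alone (relative median -0.25, adjusted p = 0.0188, and adjusted p = 0.262 with an estimated correlation); with spike-in scaling 2 were higher and 1 lower, and the list did not pass when arrays were centred (adjusted p = 0.07; range 0.000532 to 0.429). Ier2 did not pass without vehicle animal 1, 2 or 4 or RG3487 animal 2 (adjusted p = 0.0538, 0.0579, 0.0638 and 0.062; range 0.0105 to 0.1).

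Proteasome genes rose in 27 of 37 and fell in 0 (28 and 0 adjusted over the list alone; relative median 0.176, adjusted p = 4.13e-07, and adjusted p = 0.22 with an estimated correlation). When arrays were centred 16 rose and 0 fell. The 37 include Psmc3ip, which is not a subunit and did not pass (0.14 ± 0.08, named after its value was seen). Psmc5 rose by 0.37 ± 0.05, Psmc3 by 0.36 ± 0.05 and Psma2 by 0.35 ± 0.06. Ribosomal protein genes rose in 21 of 41 and fell in 0 (28 and 0 adjusted over the list alone; relative median 0.107, adjusted p = 7.91e-05, and adjusted p = 0.453 with an estimated correlation), with 7 higher and 0 lower when arrays were centred. Rpl23 rose by 0.37 ± 0.06, and Rps27l, also a known p53 target, by 1.12 ± 0.14. Heat shock genes rose in 7 of 13 and fell in 0, as when adjusted over the list alone (relative median 0.187, adjusted p = 0.0314, and adjusted p = 0.435 with an estimated correlation). Only 3 rose when arrays were centred and 4 with quantile normalization, with 0 lower in both. Dnaja1 rose by 0.34 ± 0.06 and Hspe1 by 0.32 ± 0.05. The heat shock call was lost without vehicle animal 5 or RG3487 animal 4 (adjusted p = 0.0554 and 0.0564), with spike-in scaling (0.0976) and with the dimmest 50% of probe sets left out (0.0659; range 0.00568 to 0.435).

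**Figure D4:**
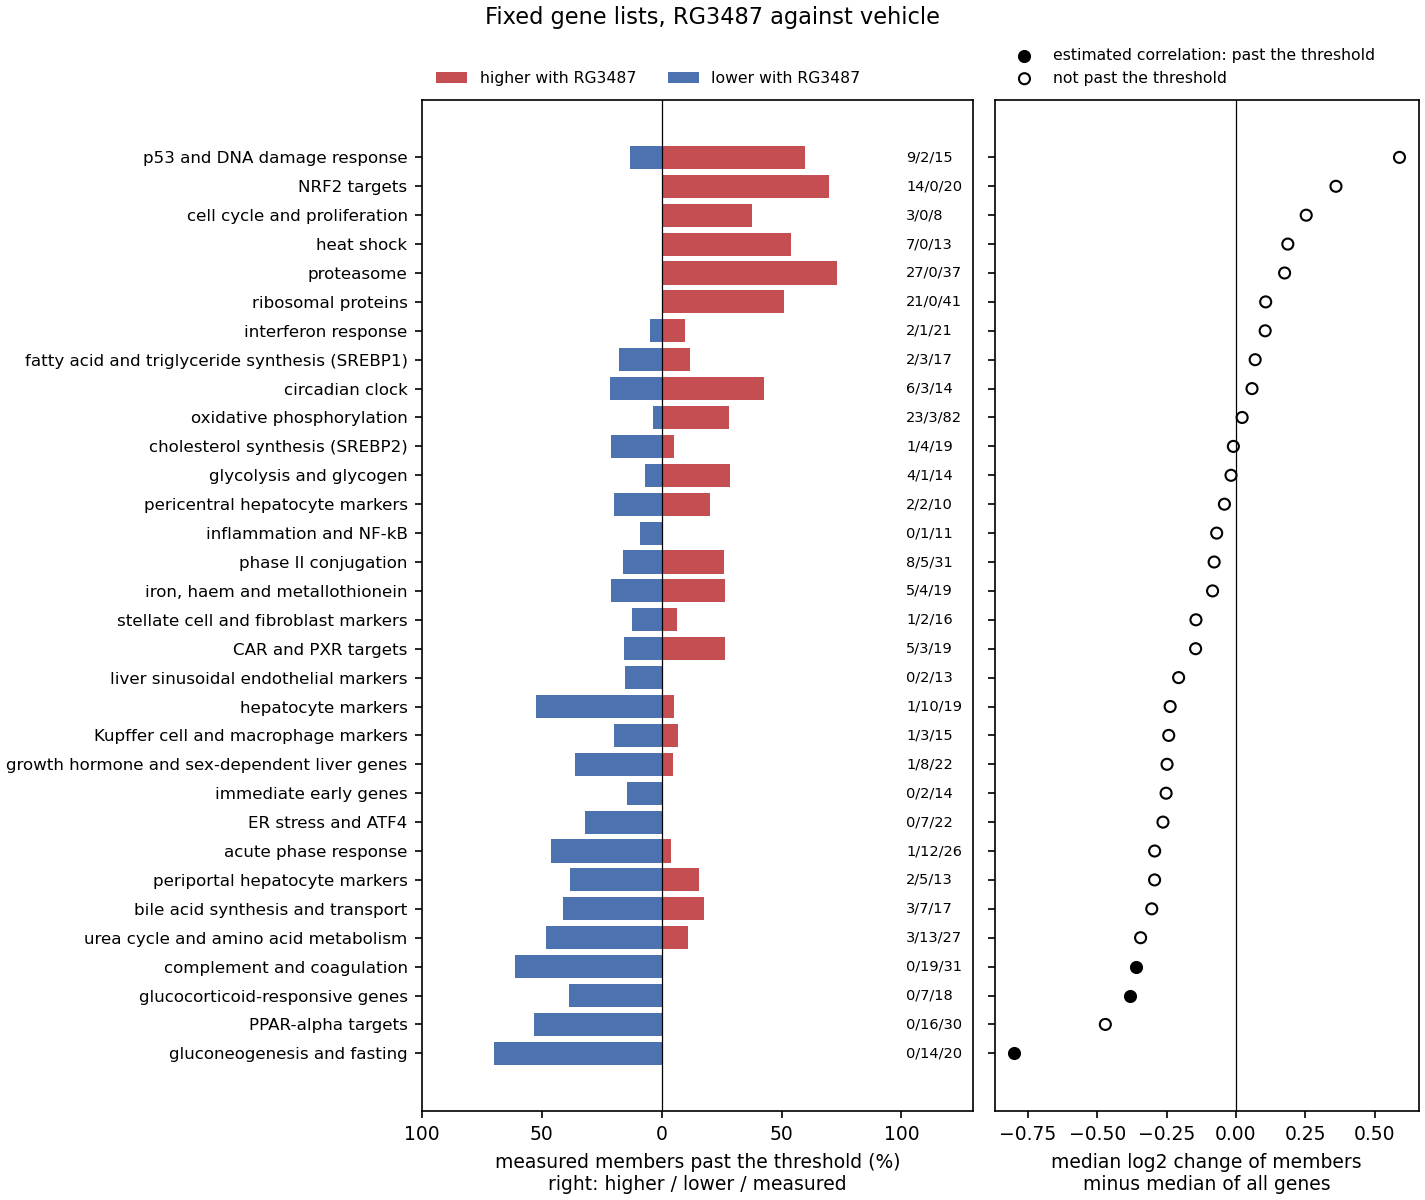
Left, the percentage of measured members of each of 32 gene lists that were higher (red) or lower (blue) with RG3487 as deposited, with the counts beside the bars; right, the median log2 change of each list minus that of all genes, filled where the list passed with an estimated correlation. The 3 filled lists lay at -0.36, -0.38 and -0.80, and 0 of the 19 lists past the threshold with the preset correlation changed sign on this axis with quantile normalization, the only scaling of the 3 that could change it. Counts in some lists did turn under other scalings.

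Several lists did not pass as a whole although members changed. Of 14 clock genes 6 rose and 3 fell (6 and 4 adjusted over the list alone). Beside Dbp, Per2 rose by 1.55 ± 0.21, while Nfil3 changed by -1.45 ± 0.21 and Rora by -0.50 ± 0.09. The list's adjusted p was 0.809, and its mean of 0.24 and its test differed in sign. Of CAR and PXR targets, 5 of 19 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.645). Their relative median of -0.15 turned positive with quantile normalization, and their mean change was 0.25. Of phase II enzymes, 8 of 31 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.461), including Ephx2 at -0.91 ± 0.12, with a mean of 0.16 and a test of the other sign. Oxidative phosphorylation genes rose in 23 of 82 and fell in 3 (26 and 3 adjusted over the list alone; adjusted p = 0.0977), with 7 higher and 6 lower when arrays were centred and 69 and 0 with spike-in scaling. The list also holds assembly factors, of which Ndufaf1, Ndufaf3 and Ndufaf8, named after their values were seen, were among the 23. It passed as higher with quantile normalization (adjusted p = 0.00686), spike-in scaling (0.00155) and no filter (0.0454), and without vehicle animal 3 or 5 or RG3487 animal 1 (0.036, 0.00799 and 0.0381; range 0.00155 to 0.753), and also under fry and the exact permutation over animals. Atp5if1 rose by 0.62 ± 0.09. In cholesterol synthesis 1 of 19 rose and 4 fell (adjusted p = 0.137), but 8 were higher and 1 lower with spike-in scaling. Relative to other genes the list passed as lower, with that scaling (adjusted p = 0.0475) and without vehicle animal 2 or RG3487 animal 4 (0.0419 and 0.0461; range 0.0419 to 0.842). In fatty acid and triglyceride synthesis 2 of 17 rose and 3 fell (adjusted p = 0.54), with 11 higher and 3 lower under spike-in scaling. Fads2, a desaturase, changed by -1.19 ± 0.16. Glycolysis genes rose in 4 of 14 and fell in 1 (adjusted p = 0.645, although fry gave a call; range 0.0251 to 0.871), and interferon genes rose in 2 of 21 and fell in 1 (adjusted p = 0.809). Iron and haem genes rose in 5 of 19 and fell in 4 (adjusted p = 0.102), which turned to 2 and 5 when arrays were centred. Inflammation genes rose in 0 of 11 and fell in 1 (adjusted p = 0.0961), with 2 higher and 1 lower under spike-in scaling, and cell cycle genes rose in 3 of 8 and fell in 0 (adjusted p = 0.0961). The cell cycle list passed without RG3487 animal 1 (adjusted p = 0.0228) and with no filter (0.00016; range 0.00016 to 0.453), and also under fry and the exact permutation. Relative to other genes the inflammation list passed as lower with spike-in scaling (adjusted p = 0.0187) and without vehicle animal 3 or RG3487 animal 5 (0.0452 and 0.0499; range 0.0187 to 0.292). For these last 7 lists the counts adjusted over the list alone were the same, except 5 and 1 for glycolysis and 5 and 5 for iron and haem. Slc2a2, the liver glucose transporter, rose by 0.61 ± 0.08, Blvrb by 0.54 ± 0.08, Ifi27l2b by 0.69 ± 0.12 and Tk1 by 0.68 ± 0.16, and Cd14 changed by -0.75 ± 0.15. Of 4 AhR targets measured, too few to test, Cyp1a1 rose. Cyp1a2 did not pass (0.09 ± 0.08, adjusted p = 0.426), but did with quantile normalization (adjusted p = 0.0232) and spike-in scaling (0.00369; range 0.00369 to 0.951). Cyp3a23-3a1 (-0.09 ± 0.07, adjusted p = 0.339) and Hmox1 (-0.17 ± 0.12, adjusted p = 0.314) did not pass. Cyp2b1 and Cyp2b2 had no probe set of their own and were not analysed here.

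Hepatocyte markers fell in 10 of 19 and rose in 1, Hnf4a (0.29 ± 0.06), or 13 and 1 adjusted over the list alone, and their counts turned to 4 higher and 1 lower with spike-in scaling. Their relative median was -0.24 (adjusted p = 2.89e-07, and adjusted p = 0.223 with an estimated correlation), and the list did not pass with quantile normalization (adjusted p = 0.846; range 1.89e-08 to 0.846). Ambp changed by -0.27 ± 0.04 as deposited and did not pass with spike-in scaling (adjusted p = 0.175; range 0.000796 to 0.175). Periportal markers fell in 5 of 13 and rose in 2 (6 and 2 adjusted over the list alone; relative median -0.29, adjusted p = 0.00919, and adjusted p = 0.388 with an estimated correlation), with 4 higher and 1 lower under spike-in scaling, and did not pass with quantile normalization (adjusted p = 0.53; range 0.000232 to 0.53). Pericentral markers rose in 2 of 10 and fell in 2 (2 and 3 adjusted over the list alone; adjusted p = 0.419), with Oat at -1.10 ± 0.20. Kupffer cell markers fell in 3 of 15 and rose in 1, Lyz2 (0.65 ± 0.16), as when adjusted over the list alone (relative median -0.24, adjusted p = 0.000249, and adjusted p = 0.223 with an estimated correlation; range 2.16e-05 to 0.223), and did not pass under fry or the exact permutation either. When arrays were centred, 7 Kupffer markers fell and 1 rose, as with quantile normalization. Sinusoidal endothelial markers fell in 2 of 13, Lyve1 (-0.36 ± 0.08) and Fcgr2b (-0.27 ± 0.08), and rose in 0, as when adjusted over the list alone (relative median -0.21, adjusted p = 0.00057, and adjusted p = 0.114 with an estimated correlation). When arrays were centred 6 fell and 0 rose, and with quantile normalization 3 and 0. With spike-in scaling the unadjusted medians of the Kupffer and endothelial lists turned positive (0.05 and 0.08) and neither endothelial gene passed. Fcgr2b did not pass without vehicle animal 2 or 5 or RG3487 animal 2 or 3 either (adjusted p = 0.0675, 0.0638, 0.0691 and 0.056; range 0.00683 to 0.471). Stellate cell markers fell in 2 of 16 and rose in 1, as when adjusted over the list alone (adjusted p = 0.0755), with 4 higher and 1 lower under spike-in scaling. Relative to other genes this list passed as lower without vehicle animal 1 or 5 or RG3487 animal 2 (adjusted p = 0.0376, 0.0221 and 0.0459) and with the dimmest 50% of probe sets left out (0.0435; range 0.0221 to 0.877). In lists too small to test, Krt18 (0.74 ± 0.10) and Krt8 (0.65 ± 0.13) of 4 cholangiocyte markers and Car2 (1.08 ± 0.19) of 4 erythroid markers rose. Fcgr2b of 2 neutrophil markers and Cela1 (-0.28 ± 0.09) of 2 adipocyte, muscle and pancreas markers fell as deposited but not with spike-in scaling, and 0 of 3 lymphocyte markers changed. Krt18, Krt8, Car2 and Cela1 were named after their values were seen. Receptors for acetylcholine and serotonin had 0 measured members. The 3' to 5' signal ratio, a measure of RNA integrity, was 3.42 ± 0.26 and 3.10 ± 0.30 for beta-actin (vehicle and RG3487, SD, n = 5, exact p = 0.119) and 1.20 ± 0.04 and 1.15 ± 0.03 for GAPDH (exact p = 0.0556). The beta-actin control probe sets rose by 0.31, 0.36 and 0.44 under exact tests as deposited and were also higher under the other 3 scalings. The middle and 5' GAPDH probe sets rose by 0.12 and 0.13 (exact p = 0.0238 and 0.0397), with 0.02 and 0.04 after centring (exact p = 0.714 and 0.635), while the 3' one changed by 0.07 (exact p = 0.198) and by -0.03 after centring. All 3 GAPDH probe sets were higher with quantile normalization (0.12 to 0.20) and spike-in scaling (0.26 to 0.33), each with an exact p under 0.05.

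In all, 19 of 32 lists passed with the preset correlation (5 up and 14 down), 3 with an estimated one, 19 with fry and 17 with the exact permutation over animals. Fry lost the urea cycle (adjusted p = 0.0948), periportal (0.247), Kupffer (0.05) and immediate early (0.182) lists. It gained the glycolysis (0.0251), cell cycle (0.0156), oxidative phosphorylation (0.0332) and clock (0.00334) lists. The exact permutation lost the bile acid (0.221), heat shock (0.0705), immediate early (0.429), growth hormone (0.109), urea cycle (0.0802), periportal (0.284) and Kupffer (0.0889) lists. It gained the cell cycle (0.0317), oxidative phosphorylation (0.0195), CAR and PXR (0.0317), clock (0.0195) and phase II (0.0195) lists. Centring and spike-in scaling shift all genes of an array alike, so only quantile normalization could change the sign of a median relative to all genes. With it 0 of the 19 changed sign, and 4 of the lists that did not pass did. Without that reference 6 of the 19 changed sign under at least 1 scaling. Housing group and treatment may coincide and cannot be told apart.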

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

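The test for a far value was fixed before any result was seen, and no pattern is weighed in this part. In 18 of 324 groups of 5 animals a single animal lay far from the other 4 by Dixon's ratio. Chance gives this in about 1 in 20 groups, or 16.2 of 324. RG3487 animal 5 was the far one in 5 of them, RG3487 animal 3 in 4 and RG3487 animal 4 in 0, and 9 animals were far in at least 1.

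In RG3487 animal 5 the signal was 5853 for Ambp (the other 4 lay at 6296 to 6450), 6924 for Gstm1 (7656 to 7717), 82 for Inmt (169 to 223) and 2913 for Rpl23 (2507 to 2563), and the mean log2 signal of ribosomal protein genes was 11.27 (11.14 to 11.17). In RG3487 animal 3 the signal was 261 for Angptl4 (465 to 564), 6568 for Cyp3a23-3a1 (5610 to 5856), 2011 for Gls2 (1306 to 1418) and 4988 for Mat1a (3839 to 3996). RG3487 animal 2 had a signal of 2545 for Hnf4a (2840 to 2950). RG3487 animal 1 had 1488 for Pdia6 (1198 to 1272) and a mean log2 signal of 9.861 for pericentral markers (10.04 to 10.09).

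Vehicle animal 3 had a signal of 1033 for Gpt (1752 to 1965) and 338 for Sdf2l1 (421 to 439). Vehicle animal 5 had 7921 for Itih4 (6976 to 7124), and vehicle animal 1 had 382 for Tkt (297 to 317). The beta-actin ratio of 3' to 5' signal was 2.971 in vehicle animal 2 (3.425 to 3.595), and the mean log2 signal of acute phase genes was 11.66 in vehicle animal 4 (11.58 to 11.6).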

How the results depend on the processing

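Scaling by the hybridization controls was tested only after the results were seen; the other alternatives were planned. That scaling gave 7037 probe sets and 4788 genes, against 3295 and 2296 as deposited; its construction raises the RG3487 arrays, on which the controls were lower, relative to the others. A fold threshold of 1.5 left 462 probe sets and 327 genes, since it adds a second condition; the exact rank-sum test called 2187 probe sets, the number whose groups did not overlap. With an estimated correlation 3 lists passed instead of 19. A higher correlation weakens this test, and most estimates lay above the preset 0.01, such as 0.526 for ribosomal proteins and 0.469 for hepatocyte markers. The bile acid list was also lost at an estimate of 0.00989, so the size of the correlation does not account for every loss. Some results changed direction and passed as reported or under the alternative, and the cause was not tested except where stated. With quantile normalization these were CAR and PXR targets (adjusted p = 0.0319; over all alternatives 0.0317 to 0.996), hepatocyte markers (0.846; 1.89e-08 to 0.846) and B2m (log2 change 0.0142). With spike-in scaling they were B2m (0.0414, against -0.15 as deposited) and Apoh (0.0155, against -0.18). That scaling raises all genes of the RG3487 arrays alike, so it turned these small decreases by construction. Set tests that do not compare a list with other genes turned CAR and PXR targets (exact, 0.0317), clock genes (fry 0.00334, exact 0.0195; over all alternatives 0.00334 to 0.954) and phase II enzymes (exact, 0.0195; 0.0195 to 0.843) from a downward sign to an upward call. Leaving out 1 array gave 2491 (without RG3487 animal 5) to 3453 probe sets (without RG3487 animal 3), 1762 to 2398 genes and 19 to 21 lists; 18 of the 19 lists passed each time, heat shock being the exception. The replicate block gave 2918 probe sets, 2027 genes and 19 lists. Comparisons of named genes with an alternative kept the side of the threshold in 2712 cases, lost the call in 151, gained it in 4 and changed direction with a call on at least 1 side in 3; for lists the counts were 795, 36, 27 and 6. Among the 2712 and 795, the sign differed without a call on either side in 4 and 14. Of 116 named genes that passed, 51 passed under every alternative run on them. The fold threshold and rank-sum test were not applied to lists. Signals near the pseudocount of 16 limit the folds of dim genes.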

Other observations

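The tests in this part were chosen only after the results they bear on were seen, except the second p53 list and the splits of the animals. Genes named only in this part, such as Cct8, Cct4, Apoa4 and Apoa5, were also chosen after their values were seen. Medians are those of the log2 change itself unless given as relative to all genes. The ± of a median is an SE from redrawing its genes with replacement, not the animals. It therefore leaves out the variation between rats and treats the genes as independent.

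In several lists written after the first results, more members rose with RG3487 than fell. This was also so among all 7727 genes as deposited, where 1724 rose and 572 fell. Subunits of the cytosolic chaperonin rose in 8 of 8 measured (Cct8 by 0.72 ± 0.09 SE, Cct4 by 0.63 ± 0.09), mitochondrial ribosomal proteins in 49 of 70 with 0 lower, and splicing factors in 28 of 42 with 0 lower. Initiation factors rose in 27 of 38, aminoacyl-tRNA synthetases in 15 of 24, ribosome biogenesis genes in 22 of 37, RNA polymerase subunits in 14 of 27 and tubulins in 4 of 6, each with 0 lower. Mitochondrial import genes rose in 13 of 21 and fell in 1, genes of the secretory pathway in 20 of 48 and 1, and ubiquitin-conjugating enzymes in 7 of 24 and 0. None of these passed with an estimated correlation (adjusted p = 0.176 for the chaperonin and 0.112 for mitochondrial ribosomal proteins). When arrays were centred the higher and lower counts were 8 and 0 for the chaperonin, 26 and 0 for mitochondrial ribosomal proteins, 17 and 1 for splicing factors, 18 and 0 for initiation factors and 7 and 1 for the synthetases. They were 12 and 0 for ribosome biogenesis, 8 and 0 for RNA polymerase, 4 and 0 for tubulins, 9 and 1 for mitochondrial import, 10 and 3 for the secretory pathway and 3 and 2 for ubiquitin-conjugating enzymes. Of keratins and actins 3 of 4 rose, and of peroxins 4 of 13 rose and 1 fell. List medians were also set against 10000 random lists matched on mean signal. Ubiquitin-conjugating enzymes, secretory genes and peroxins lay at percentiles 87.58, 91.32 and 57.65, so their rise was not unusual for genes of their signal. The other lists of this paragraph lay at 99.8 or above, except keratins and actins, which were too few to test.

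Serpins fell in 11 of 20 and acyl-CoA dehydrogenase and beta-oxidation genes in 16 of 26, each with 0 higher (adjusted p = 0.0323 with an estimated correlation for both); with spike-in scaling 2 serpins were higher and 5 lower, and 1 oxidation gene was higher and 11 lower. Apolipoproteins fell in 9 of 13 and rose in 0 (adjusted p = 0.112 with an estimated correlation), with Apoa4 at -0.94 ± 0.07 and Apoa5 at -0.54 ± 0.08. Only 2 were lower with spike-in scaling, where their median turned positive (0.0155), and 3 with quantile normalization (relative median -0.0548). Their median lay at percentile 15.1 of random lists matched on mean signal, so their fall was not unusual for genes of that signal. Serpins lay at percentile 0.03 and the oxidation genes at 0. Lysosomal genes rose in 5 of 34 and fell in 10, CYP2 genes in 3 and 8 of 19, and solute carriers in 23 and 22 of 143 (relative median -0.09, adjusted p = 0.0323 with an estimated correlation); with spike-in scaling these were 13 and 4, 5 and 5, and 58 and 8, and 13 and 32 solute carriers when arrays were centred. Genes outside the families had been taken into 5 of the later lists, and were removed after the counts were seen. The first counts of higher and lower genes were 27 and 1 of 46 initiation factors, 4 and 0 of 10 tubulins (adjusted p = 0.0559, and 0.00875 after the correction), 22 and 0 of 40 ribosome biogenesis genes, 22 and 1 of 54 secretory genes and 2 and 16 of 28 oxidation genes.

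As deposited, more probe sets rose than fell, while among the 773 brightest genes 178 were higher and 209 lower. Compression of bright signals would lower bright hybridization controls relative to dim ones, but the 9 brighter controls lay 0.0723 ± 0.023 (SE) above the 9 dimmer ones in log2 change, whereas the brightest genes lay at -0.12 ± 0.03 relative to the rest. Fewer hepatocytes would raise markers of other cells, but the median of 44 Kupffer, endothelial and stellate markers was -0.205 ± 0.016 relative to all genes. That of 4 cholangiocyte markers was 0.365, but of these only the keratin genes Krt8 and Krt18 passed. Whether these 2 genes mark other cells here was not tested, so the cholangiocyte list cannot decide. The scaling of each array to a common mean may account for the balance, but the test of it decides nothing: centring puts the median change near 0 by construction, so the 45.1% of calls that were higher after it cannot speak for or against this, and the effect of scaling and a true excess of increases cannot be told apart. A response of the liver to RG3487 was not tested against these.

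Cyp2c12, a gene expressed mainly in female rat liver, rose. Rats of another sex in the RG3487 group would lower male-specific and Y-linked genes strongly, but the median change of 6 such genes was -0.0857 ± 0.126 (-0.18 relative to all genes), with a range of -0.26 to 0.36. A change in growth hormone signalling may also raise Cyp2c12, but the 8 female-biased genes, Cyp2c12 among them, had a median of -0.207 ± 0.251 (-0.28 without Cyp2c12) and the 14 male-biased genes one of -0.11 ± 0.06, or -0.302 and -0.206 relative to all genes. The rule written for this test counted a female-biased median of the other sign against this explanation. That median was below 0, at percentile 1.64 of random lists matched on signal. The female-biased list passed as lower with the preset correlation (adjusted p = 0.0461). It did not with an estimated correlation (adjusted p = 0.176) or the exact permutation over animals (adjusted p = 0.794). The spread of these genes is too large to decide, so this explanation stays open.

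Members of the clock list (6 higher and 3 lower of 14) and of the fasting list both changed with RG3487. The clock list did not pass as a whole with the preset correlation (adjusted p = 0.809). Whether the members of the 2 lists changed together across animals was not tested. A different clock phase of the RG3487 livers is a candidate explanation: among 12 measured evening and morning genes named for this test, 7 passed and 7 went with a single shift, the evening genes Per2, Dbp, Nr1d1, Nr1d2 and Tef upward and the morning genes Nfil3 and Bmal1 downward, while Cry2 (0.57) and Rora (-0.50) also passed but were not named for it. The 2 evening and 3 morning genes that did not pass were not scored. The groups were written after clock values had been seen, so this count is no independent test. Whether RG3487 or the hour of harvest moved them was not tested, since harvest hours are not given in the sources used here. Different food intake may lower fasting genes (0 higher and 14 lower passed) and raise lipogenic genes, whose median was 0.202 ± 0.13 over 6 measured. This lies between what feeding and no feeding were set to show, as does 0.107 when arrays were centred or with quantile normalization, whereas 0.397 with spike-in scaling reaches what feeding was set to show but 1 fasting gene was then higher, so food intake and a direct effect cannot be told apart.

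Because p53 targets rose, a second list of p53 targets was written before its values were seen, with the hypothesis that it may rise too. As deposited 1 of 19 measured rose and 1 fell, and its median of 0.0035 ± 0.036 (-0.0909 relative to all genes) lay at percentile 8.56 of 10000 lists matched on signal, so it did not rise relative to other genes. The counts depended on the scaling, with 8 higher and 0 lower under spike-in scaling and 0 and 2 when arrays were centred.

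Among 100 splits of the 10 animals into groups of 5, the real split was the only 1 to give as many as 3295 probe sets or 2296 genes (highest other 2 and 2). The lowest share that 100 splits can give is 1 of 100, so chance is unlikely for these counts but not excluded. A difference between housing groups could follow the same split. For lists, 12 splits, the real one among them, gave 19 or more (highest other 21). Most of the others kept 4 of the 5 vehicle animals together and so carried much of the real contrast. Splits with 3 together also reached 19 lists, with 0 genes past the threshold. The rule fixed beforehand set chance aside only if under 5% of splits reached the real number, and this was not met. Chance is therefore not set aside for the number of lists that passed with the preset correlation. How much of that number it gives cannot be told, since splits that carried the real contrast were counted too. The replicate numbers did not pair the animals: correlations of animals with the same number were -0.0371 to 0.174, and 1 of 5 numbers correlated best with its own.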
